A study of Mus musculus with 13 samples.

How the data were processed

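RNA of 13 mouse samples was hybridised to Affymetrix gene arrays, 1 sample per array. Per the labels' protocols, glands were freed with EDTA, the sorted cells were also trypsinized and separated by flow cytometry, RNA was extracted with Trizol and purified on RNeasy columns, and biotin-labelled with the One-Cycle cDNA kit. Whole glands were processed directly per the labels, so handling differs between glands and sorted cells and cannot be told apart from cell type there. The authors deposited log2 values for 35556 probesets per array, which, per the submitters' processing notes, come from RMA and Affymetrix Power Tools; versions and the background settings are not given in the sources used here. RMA makes arrays comparable by giving them nearly the same distribution of values, so a change shared by most genes would not show, and bright genes near 13 have little room to differ. No detection call was used, so a gene below an array's median is not shown to exceed background, and the size of its difference is open.

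Gene names came from the platform annotation of the probesets. Of the probesets 21218 had 1 gene symbol, 1881 had several and 12457 had none, and 21185 of the single-symbol probesets were matched to the mouse RefSeq table (assembly GRCm38.p6), with 0 symbols updated. Each gene was represented by its single-symbol probeset with the highest mean over the arrays of the fit, which left 18820 genes, 1386 of them with several probesets. Probesets with several symbols or none entered only the alternative that tests every probeset and a separate count for the organoids, and were not named.

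Groups followed the sample titles. The 7 arrays of the first experiment were fitted together with a mean per group, and the 6 organoid arrays in a fit of their own, with lmFit and eBayes of limma 3.58.1 (R 4.3.3, statmod 1.5.0), without a block. Adjusted p-values are Benjamini-Hochberg values from limma over all genes of a comparison, with a threshold of 0.05. They measure the spread between arrays; the labels do not say that the organoid cultures came from different animals. Before the data were examined, 25 gene lists with 348 entries were fixed for cell types and pathways. Lgr5, Ascl2 and Tnfrsf19 stand in both the stem cell and the Wnt list, and Cd44 and Sox9 in both the metaplasia and the Wnt list. Results of these lists therefore share genes. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The erythrocyte list had fewer measured genes and was not tested. A count adjusted over the list alone repeats the Benjamini-Hochberg step within that list.

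The named genes were chosen by a rule set before the data were examined: Tnfrsf19, the 6 genes with the largest positive and the 6 with the largest negative change past the threshold with no overlap between groups, and from each list up to 4 genes past the threshold, or the 2 brightest where none passed. From this set the text prints Tnfrsf19, genes past the threshold and the examples of lists past their test, a limit on length set after the data were seen that does not look at how stable a gene's value was. It left out 26 of 51 genes in chief against parietal cells, 26 of 58 in chief cells against glands, 26 of 62 in parietal cells against glands and 8 of 76 in organoids. Of those, Krt5 in chief against parietal cells and Cela1 in organoids are still named, the former for its levels on single chief arrays and the latter for its value with the block. Of the genes left out, 8, 11, 6 and 4 changed sign under at least 1 alternative. Genes named outside the rule are said to be so.

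The organoid letters were taken to pair the arrays. Deviations from the group means correlated at 0.184, 0.232 and 0.386 for the same letter, above every other pairing of the same arrays. The labels do not state this pairing, and the main fit left it out. In the first experiment 2 letters were shared by all groups. Deviations of the same letter correlated at 0.263 and 0.111 between chief and parietal arrays. Between chief and gland arrays these were -0.194 and 0.0694, and between parietal and gland arrays 0.0267. This did not settle whether equal letters mark pairs, and letters were taken as names only.

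Tests were checked on simulated data with 200 changed genes per comparison. At a log2 change of 2, 74% were recovered for chief against parietal cells, 86% for chief cells against glands, 72% for parietal cells against glands and 96% for organoids. At a log2 change of 1 these were 16%, 18%, 18% and 84%. False calls made up 2.1%, 6.54%, 5.11% and 5% of the calls. The simulated noise was drawn independently for each gene and array. Shifts shared by many genes of 1 array were therefore absent, and these rates need not hold for the measured arrays.

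Alternatives were repeated quantile normalization, centring arrays on their median, leaving out dim features, eBayes with trend and robust, array weights, all 13 arrays in 1 fit, only the groups compared, every probeset, a 2-fold threshold beside the adjusted p, the replicate letter as a block, leaving out each array of the 2 groups compared, and for lists an estimated correlation. Testing the 2 lists that hold Tnfrsf19 without it was added after the data were seen. Leaving out arrays for the lists was added after chief replicates b and c and ER replicate b were seen to stand apart.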

Results

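RNA from 13 samples of the mouse stomach was measured on gene expression arrays in 2 experiments. The cells carried a fluorescent reporter in the Tnfrsf19 locus; Tnfrsf19 encodes Troy, a receptor of the TNF receptor family. In the first experiment, reporter-positive chief cells (3 arrays) and reporter-positive parietal cells (2 arrays) were sorted from glands of the gastric corpus, with about 100000 sorted cells from 10 mice per array, and 2 arrays of whole corpus glands served as the reference. Chief cells secrete digestive enzymes and parietal cells secrete acid. In the second experiment, organoids grown from single reporter-positive chief cells were kept in a full medium (EGFNWR, 3 arrays) or in a reduced medium with only EGF and Rspondin (ER, 3 arrays). The full medium also held Wnt3a, Noggin, FGF10 and the hormone gastrin. Levels are log2 intensities, differences are log2 fold changes with the standard error (SE) of the fit, and array medians lay between 5.01 and 5.30. The number of arrays limits the precision of every value. One protocol text in the labels names intestines as the tissue of the sorted cells, while the other labels name the gastric corpus, which is followed here.

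The first question was how sorted chief cells differ from sorted parietal cells. As groups, the fixed lists of proliferation genes, immediate early and stress genes, chief cell genes and mucous neck cell genes were higher in chief cells, and the lists of oxidative phosphorylation, parietal cell and fatty acid oxidation genes were higher in parietal cells. These calls come from limma's camera test with its preset correlation. None held with an estimated correlation, where the adjusted p was 0.493 for the lists higher in chief cells and 0.528 for those higher in parietal cells. The mean log2 fold change was 1.23 over 22 proliferation genes, 1.28 over 16 immediate early genes, 1.19 over 9 chief cell genes and 0.94 over 5 mucous neck cell genes. It was -0.69 over 31 oxidative phosphorylation genes, -0.72 over 16 parietal cell genes and -0.64 over 14 fatty acid oxidation genes, and without chief replicate b these means were -0.32, -0.38 and -0.31. No single gene passed limma's threshold, and 2279 of 18820 genes had an unadjusted p under 0.05. Tnfrsf19, the gene that was sorted on, was 7.97 ± 0.55 (SD, n = 3) in chief cells and 8.52 ± 0.28 (SD, n = 2) in parietal cells, a log2 difference of -0.54 (SE 0.33, limma adjusted p = 0.536).

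The single genes of these lists are given as values, since none passed. Among proliferation genes, the mitotic cyclin Ccnb2 differed by 2.08 (SE 0.50) and the replication factor Pcna by 0.24 (SE 0.18), and adjusted over the list alone 15 of the 22 genes were higher in chief cells. Adjusted over the list alone, 15 of the 16 immediate early genes were higher, among them Btg2 with 1.31 (SE 0.36) and Jun with 0.96 (SE 0.32). In the chief cell list 6 of 9 genes were higher when adjusted over the list alone, while its brightest members, pepsinogen C (Pgc) and colipase (Clps), stood near 13.5 in chief cells, close to the top of the scale, and differed by 0.29 (SE 0.18) and 0.19 (SE 0.18). The proton pump genes Atp4b and Atp4a, which mark parietal cells, were 13.01 ± 0.32 and 12.97 ± 0.31 (SD, n = 3) in chief cells and 13.26 ± 0.05 and 13.12 ± 0.06 (SD, n = 2) in parietal cells. Their differences were -0.25 (SE 0.22) and -0.15 (SE 0.23). Chief replicate b was the lowest chief array for both, at 12.65 and 12.62. Over the 16 parietal cell genes, chief cells minus glands had a mean of 0.04. With the replicate letter as a block, where chief c drops out, that mean was -0.23. As a list mean, parietal cell transcripts in the sorted chief cells thus lay near the level of glands, but arrays and members differed. Kcnj16 was 10.35, 8.73 and 11.05 in chief a, b and c, against 11.19 and 10.92 in glands. Aqp4 went the other way, at 9.92, 7.91 and 10.29 against 8.34 and 6.76. Chief b was the lowest and chief c the highest chief array for both, which were chosen after their values were seen. The gland mucin Muc6 differed by 0.85 (SE 0.27) and Tff2 by 0.57 (SE 0.23), with 4 of 5 mucous neck cell genes higher when adjusted over the list alone. These counts for the proliferation, immediate early, chief cell and mucous neck cell lists were 0, 2, 1 and 1 without chief replicate a and 8, 1, 4 and 1 without chief b. They were 0, 0, 0 and 1 without parietal a and 0 in all 4 lists without parietal b. The lists of metaplasia genes (mean 0.62; Clu 1.29, SE 0.31; Mal2 -0.40, SE 0.25), stem cell candidates (0.54; Prom1 1.37, SE 0.41, with -0.355 on a second, dimmer probeset; Lrig1 -0.41, SE 0.29) and Notch genes (0.56; Notch1 1.59, SE 0.57; Hes1 1.43, SE 0.52) were also higher in chief cells at the preset correlation. With an estimated correlation the adjusted p was 0.493 for metaplasia genes and 0.528 for the stem cell and Notch lists. The lists of Wnt targets (0.32; Sox9 0.87, SE 0.24; Znrf3 0.24, SE 0.24) and protein folding genes of the endoplasmic reticulum (0.50; Calr 0.53, SE 0.25; Xbp1 0.53, SE 0.32) were higher at the preset correlation, with an adjusted p of 0.528 with an estimated one. Without chief replicate b the means were 0.34 for Notch genes and 0.20 for Wnt targets. Adjusted over the list alone, 5 of 10 metaplasia genes, 5 of 14 stem cell candidates, 3 of 18 Wnt targets and 1 of 19 folding genes were higher, and 1 stem cell candidate was lower. The metaplasia count was 0 without parietal b. Those of the stem cell, Wnt and folding lists were 0 without chief a, without chief b, without parietal a and without parietal b, and 7, 5 and 15 without chief c. In limma's test adjusted over the list alone, 0 of 12 Notch genes, 0 of 31 oxidative phosphorylation genes, 0 of 16 parietal cell genes and 0 of 14 fatty acid oxidation genes passed. At an unadjusted p under 0.05, 4 Notch genes were higher and 1 lower, and 6, 2 and 3 genes of the other lists were lower. Without chief c, 5 Notch genes were higher and 21, 4 and 6 genes of the other lists lower when adjusted over the list alone. The mitochondrial genes Cox6c and Cox7b differed by -0.40 (SE 0.25) and -0.38 (SE 0.23), Hadh by -0.26 (SE 0.21) and Etfb by -0.36 (SE 0.29). Chief replicate b was the lowest chief array for each of them, at 12.06, 11.93, 11.37 and 10.15, so these differences lean on that array.

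In all, 12 lists passed at the preset correlation. Lists for pit, enteroendocrine and tuft cells, BMP targets, FGF and MAPK feedback, interferon and MHC genes, leukocytes, stroma, endothelium, pancreatic acinar cells, intestine and squamous forestomach did not pass. The squamous list had a mean of 1.02, and of 0.02 without chief replicate b, with Krt5 at 11.85 in chief replicate b and at 6.37 and 4.25 in replicates a and c. Across all probesets, chief replicate c correlated with the parietal arrays at r = 0.979 and 0.982, and with the other chief arrays at 0.950 and 0.961. Without chief replicate c, one of the arrays left out in turn as set beforehand and singled out here after the data were seen, 909 genes were higher and 408 lower in chief cells. The genes named next were also chosen after their values were seen. Pepsinogen 5 (Pga5) was then 3.40 (SE 0.23) higher, the mucin glycosyltransferase A4gnt 3.17 (SE 0.34), Top2a 3.13 (SE 0.29) and Mki67 2.87 (SE 0.36), and the histamine receptor Hrh2 fell by 2.21 (SE 0.27) on the log2 scale. Top2a lay at 4.99 and 4.91 on the parietal arrays, below their medians, where signal is not shown to exceed background, so the size of its difference is open. In that fit 19 of 22 proliferation genes, 12 of 16 immediate early genes and 3 of 9 chief cell genes were higher, with 8 folding genes, 6 stem cell candidates, 4 genes each of the metaplasia, Wnt and Notch lists and 1 mucous neck cell gene. Lower were 2 genes each of the parietal cell, oxidative phosphorylation and fatty acid oxidation lists. These counts cover only the 12 lists that had passed. With the replicate letter as a block, where chief c also drops out, 3 BMP targets were lower and 1 higher. In the FGF and MAPK feedback list 4 genes were then higher and 1 lower. Without chief replicate b the Notch list lost its call (adjusted p = 0.0688), without parietal replicate b the list of Wnt targets did (adjusted p = 0.153), and with all 13 arrays in 1 fit the mucous neck cell list (adjusted p = 0.0907) and the Wnt targets (adjusted p = 0.0504) did. Calls were gained by the pit list without chief b (adjusted p = 0.00446, mean 0.58, against 0.27 with all arrays and -0.27 without chief a), the squamous list without chief a (0.00486), chief c (0.0357) or parietal b (0.0462), and the FGF and interferon lists without parietal a (0.0378 and 0.0347).

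**Figure D1:**
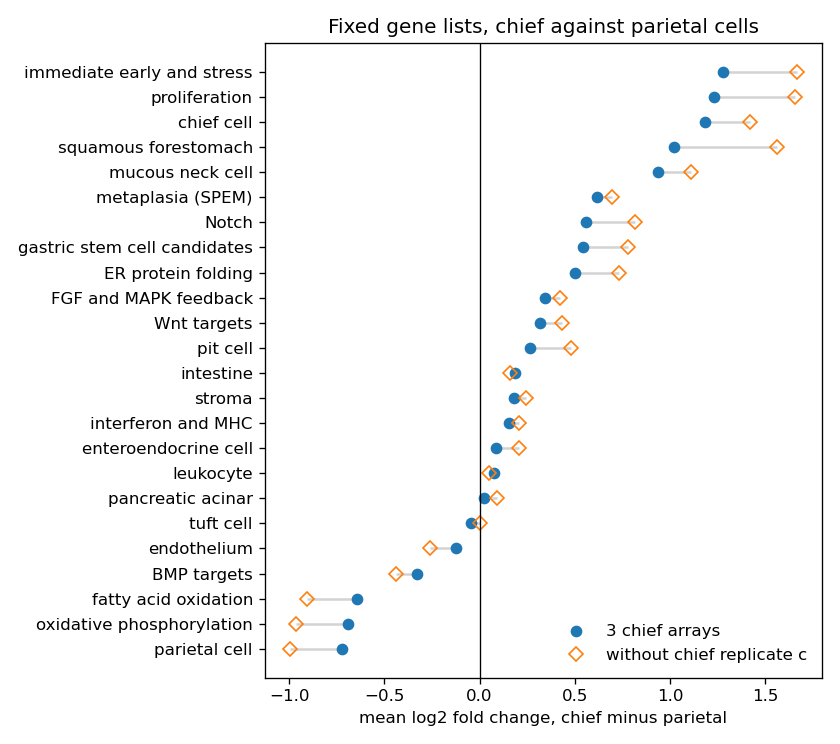
Mean log2 fold change (chief minus parietal, x axis) of each fixed gene list (y axis), with 3 chief arrays (filled circles) and without chief replicate c (open diamonds); ER in a list name stands for endoplasmic reticulum. Proliferation genes stand at 1.23 and 1.66, chief cell genes at 1.19 and 1.42, and oxidative phosphorylation genes at -0.69 and -0.97.

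Sorted chief cells were next compared with whole glands. Chief cells had more Tnfrsf19 (7.97 ± 0.55, SD, n = 3, against 5.16 ± 0.34, SD, n = 2), with a log2 fold change of 2.81 (SE 0.33, limma adjusted p = 0.0199), and more Lgr5, a Wnt target and stem cell marker (3.68, SE 0.46, adjusted p = 0.0263). Among immediate early and stress genes, Fosb rose by 5.19 (SE 0.59, adjusted p = 0.019), Atf3 by 5.14 (SE 0.22, adjusted p = 0.000126), the phosphatase Dusp1 by 3.52 (SE 0.27) and Gadd45b by 3.06 (SE 0.23). The small nucleolar RNAs Snora33 (-6.10, SE 0.21), Snord118 (-5.47, SE 0.30), Snora69 (-5.14, SE 0.19) and Snora74a (-3.88, SE 0.41), of a class that guides the modification and processing of ribosomal RNA, were lower. Of 59 small nucleolar and Cajal body RNAs measured, a class counted after its values were seen, 16 were lower and the rest did not pass. Snora33, Snord118 and Snora69 lay between 4.04 and 5.13 in chief cells, below the array medians, where signal is not shown to exceed background. The size of such a difference is therefore open, and the same holds for Rgs13, Dclk1, Trpm5, Gnat3 and Vaultrc5 in chief cells and Fam71a in glands. Mogat1 lay below the median on 2 of 3 chief arrays and Tnfrsf19 on 1 of 2 gland arrays. In all, 24 genes were higher and 66 lower in chief cells, and 2832 had an unadjusted p under 0.05.

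In the tuft cell list 4 of 10 genes were lower: Rgs13 by -3.56 (SE 0.22), Dclk1 by -2.53 (SE 0.23), the taste channel Trpm5 by -1.91 (SE 0.29) and the taste G protein Gnat3 by -1.90 (SE 0.21). Without glands replicate b, 1 tuft cell gene was lower. A second, dimmer probeset of Dclk1 differed by 0.39. In the enteroendocrine list 2 of 12 genes were lower, the histamine-forming enzyme Hdc (-2.50, SE 0.32) and somatostatin, Sst (-2.07, SE 0.26). Without chief replicate b, 0 of them passed. Among immediate early and stress genes 8 of 16 were higher, and 15 when adjusted over the list alone. The 8 became 3 without chief b, 14 without chief c, 4 without glands a and 3 without glands b. The sorted cells had been trypsinized and passed through the sorter, whereas glands were processed directly. Of the Wnt targets and of the stem cell candidates, 2 of 18 and 2 of 14 were higher, in both cases Lgr5 and Tnfrsf19, the gene the cells were sorted on, and 11 and 4 when adjusted over the list alone. Tested without Tnfrsf19, the Wnt list kept its call at the preset correlation (adjusted p = 9.58e-07) and the stem cell list lost it (adjusted p = 0.0637); with an estimated correlation these were 0.409 and 0.593. In each list 1 passed without chief b and 0 without glands b, and without chief c 5 Wnt targets passed. Adjusted over the list alone, 6 Wnt targets were higher without glands b and 7 stem cell candidates without chief c. The pit cell list, genes of the mucous surface, had a mean of -1.82 and no gene past the threshold, with 8 of 10 lower when adjusted over the list alone, a count that was 2 without chief b, 2 without chief c, 3 without glands a and 0 without glands b. Without chief a, 6 pit cell genes passed the threshold over all genes, with a mean of -2.35, and without glands a 1 did. Its member Gkn2 differed by -1.28 (SE 0.50) and Psca by 0.06 (SE 0.17). Across all probesets chief replicate a correlated with glands a and b at r = 0.978 and 0.966, and with chief b and c at 0.953 and 0.950. Its Muc5ac, a gene chosen after its values were seen, was 12.01 against 9.84 and 9.87 in the other chief arrays and 12.47 and 12.83 in glands. Proliferation genes had a mean of -0.81 with none past the threshold (Ccnb2 -1.26, SE 0.50; Pcna 0.03, SE 0.18). That mean was -0.38 without chief c and -1.12 without chief b, where 18 of 22 were lower when adjusted over the list alone, against 1 with all chief arrays. Chief cell genes had a mean of 0.85, also with none past it (Pgc 0.24, SE 0.18; Clps 0.21, SE 0.18), and 0.49 without glands b. The means were 0.36 for endoplasmic reticulum folding genes (Xbp1 0.04, SE 0.32; Calr -0.01, SE 0.25) and -0.64 for interferon and MHC genes (B2m -0.27, SE 0.18; H2-K1 -0.31, SE 0.39), with none past the threshold in either. The former was 0.22 without chief a and 0.59 without chief c, and the latter -1.20 without glands a and -0.07 without glands b. The squamous list had a mean of 1.31 with none past it (Krt5 3.19, SE 1.82; Krt14 1.61, SE 1.19) and came from chief replicate b, without which its mean was 0.31. Adjusted over the list alone, 7 of 10 tuft cell, 2 of 12 enteroendocrine and 3 of 15 interferon genes and 1 of 18 Wnt targets were lower and 4 of 9 chief cell genes higher, while 0 folding and 0 squamous genes passed limma's test (3 and 1 higher at an unadjusted p under 0.05). Without chief c 1 folding gene passed, and 9 of 19 when adjusted over the list alone, and without chief a 1 squamous gene passed. Without glands a, 2 chief cell and 5 interferon genes passed the threshold over all genes. The chief cell count over the list alone was 0 without chief a, 1 without chief b and 0 without glands b. The interferon count was 0 without chief a, 0 without chief b, 1 without chief c, 9 without glands a and 0 without glands b, and that of lower Wnt targets 0 without glands a. Outside the lists called, the gastrokine Gkn3 rose by 2.43 (SE 0.37), and Fam71a rose by 5.08 (SE 0.26), while the acyltransferase Mogat1 fell by 4.90 (SE 0.66) and the vault RNA Vaultrc5 by 3.89 (SE 0.32), all on the log2 scale.

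These 11 lists passed camera with the preset correlation. None passed with an estimated correlation, with adjusted p between 0.341 and 0.593. Lists for parietal, mucous neck and metaplasia cells, BMP targets, FGF and MAPK feedback, Notch, oxidative phosphorylation, fatty acid oxidation, leukocytes, stroma, endothelium, pancreatic acinar cells and intestine did not pass. Each chief and gland array weighed on the count, while the parietal arrays, which share the fit, were not left out here. It was 223 higher and 217 lower without chief replicate a, 5 and 20 without chief b, 107 and 78 without chief c, 45 and 198 without glands a, and 4 and 13 without glands b. Of the named genes, 9 of the 20 that passed did so under every alternative. List calls ended without chief a (chief cell, adjusted p = 0.0606; stem cell candidates, 0.151; endoplasmic reticulum folding, 0.189; interferon and MHC, 0.0643), without chief b (stem cell candidates, 0.142; endoplasmic reticulum folding, 0.0902; squamous, 0.142), without chief c (interferon and MHC, 0.053), without glands a (squamous, 0.0816), without glands b (interferon and MHC, 0.374), without dim features (interferon and MHC, 0.432) and with all 13 arrays in 1 fit (stem cell candidates, 0.0737). Calls were gained by the lists of oxidative phosphorylation (without chief b, 0.000663, mean 0.29; without chief c, 0.000889, mean -0.35), endothelium (without chief b, 0.0476; without glands b, 0.0456), BMP targets (without chief c, 0.0251; without glands a, 0.0198), intestine (without chief c, 0.0185; without glands a, 0.00513), FGF and fatty acid oxidation (without chief c, 0.0414 and 0.0104) and stroma (without glands b, 0.0456).

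**Figure D2:**
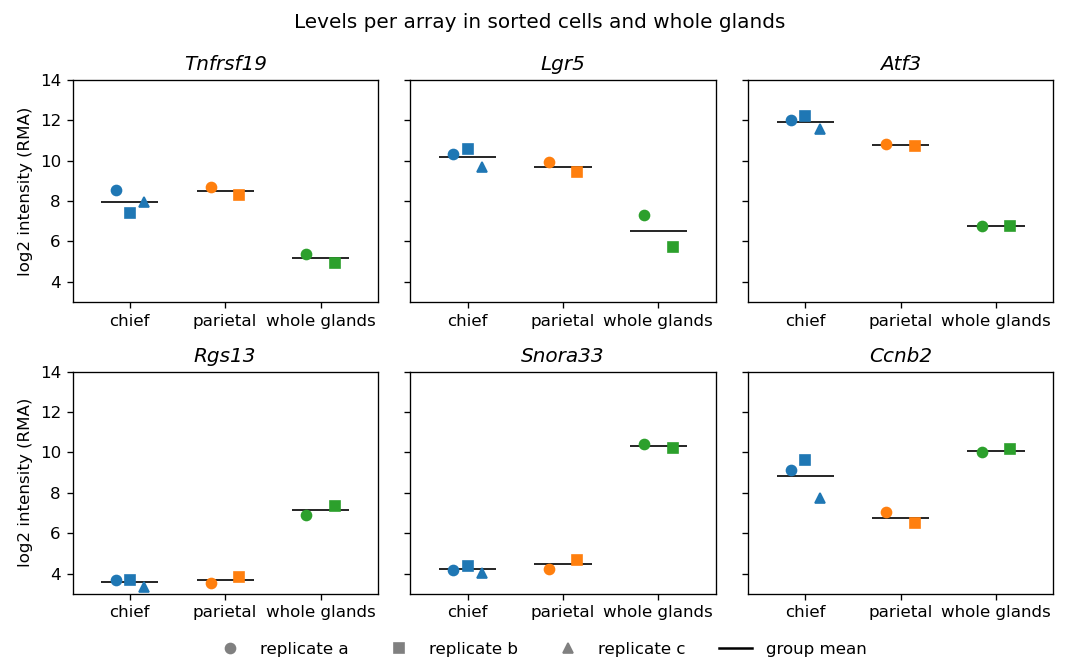
Log2 intensity (y axis) of 6 genes on each array of sorted chief cells, sorted parietal cells and whole glands (x axis); symbols mark the replicate letter and horizontal lines the group mean. Atf3 lies at 6.78 in both gland arrays and between 10.74 and 12.21 in the sorted cells, and Snora33 at 10.20 and 10.40 in glands and at most 4.68 in the sorted cells.

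Sorted parietal cells were compared with the same glands. They had more Tnfrsf19 (8.52 ± 0.28, SD, n = 2, against 5.16 ± 0.34, SD, n = 2; log2 fold change 3.36, SE 0.36, limma adjusted p = 0.0167), more Lgr5 (3.18, SE 0.51, adjusted p = 0.0363) and more Lrig1, a feedback inhibitor of EGF receptors (1.87, SE 0.31). The cell division genes Ccnb2 (-3.34, SE 0.55), Bub1, a checkpoint kinase (-2.98, SE 0.54), Tk1, thymidine kinase (-2.50, SE 0.35) and Rrm2 (-2.38, SE 0.43) were lower. The stress genes Atf3 (4.00, SE 0.24, adjusted p = 0.00126), Fosb (3.61, SE 0.65), Dusp1 (2.44, SE 0.30) and Gadd45b (2.31, SE 0.26) were higher in these trypsinized and sorted cells. The small nucleolar RNAs Snora33 (-5.84, SE 0.23), Snord118 (-5.60, SE 0.33) and Snora69 (-5.22, SE 0.21) were lower, and of the 59 RNAs of that class 27 were lower and the rest did not pass. On the parietal arrays Snora33 and Snord118, like Rgs13, Dclk1, Gnat3, Trpm5, Bub1, Mogat1 and Cpa3, lay below the array medians, and Snora69 lay at 5.18 and 4.78. Fam71a and Itga9 lay below the medians in glands, so the size of these differences is open too. Cyp2c65 and Aldh3a1 lay below the median on 1 of 2 parietal arrays. In all, 43 genes were higher and 260 lower, and 3932 had an unadjusted p under 0.05. The SE of these differences also takes in the spread of the chief arrays, which share the fit and were not left out here. With only the 2 groups compared in the fit, 1205 genes were higher and 1508 lower. The main counts therefore do not rest on the spread of parietal and gland arrays alone.

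Of the proliferation genes 4 of 22 were lower, and 21 when adjusted over the list alone, with a mean of -2.04. The tuft cell list had 5 of 10 genes lower, among them Rgs13 (-3.46, SE 0.24), Dclk1 (-2.40, SE 0.25; 0.43 on a second, dimmer probeset), Gnat3 (-1.99, SE 0.23) and Trpm5 (-1.94, SE 0.32). In the enteroendocrine list Hdc (-2.12, SE 0.35) and Sst (-1.76, SE 0.29) were lower, and in the metaplasia list Dmbt1 (-2.24, SE 0.31) and Wfdc2 (-2.13, SE 0.37). The pit cell list had a mean of -2.08 with none past the threshold (Gkn2 -1.30, SE 0.55; Psca 0.12, SE 0.19) and 8 of 10 lower when adjusted over the list alone. The pit count was 0 without parietal a, without parietal b and without glands b. Among immediate early genes 4 of 16 were higher, and 8 when adjusted over the list alone, a count that was 4 without parietal a and 5 without glands a. Of the Wnt targets Lgr5 and Tnfrsf19, the gene sorted on, were higher, and tested without Tnfrsf19 the list had an adjusted p of 0.0454 at the preset and 0.658 with an estimated correlation. Without parietal a, and likewise without parietal b, 0 genes passed in the proliferation, tuft cell, enteroendocrine, metaplasia, immediate early and Wnt lists. Without glands b 1 passed in the tuft cell and immediate early lists and 0 in the others, and without glands a 1 proliferation gene and 0 enteroendocrine and metaplasia genes did. Parietal cell genes had a mean of 0.77 with none past the threshold, and the proton pump genes Atp4b and Atp4a, near the top of the scale, differed by 0.32 (SE 0.25) and 0.36 (SE 0.25). Oxidative phosphorylation genes had a mean of 0.61 with none past it (Cox6c 0.34, SE 0.28; Cox7b 0.35, SE 0.25). Interferon and MHC genes had a mean of -0.79, also with none past it (B2m -0.28, SE 0.19; H2-K1 -1.49, SE 0.43), and -1.35 without glands a and -0.22 without glands b. Adjusted over the list alone, 6 tuft cell, 5 enteroendocrine, 3 metaplasia and 2 Wnt genes were lower, 3 parietal cell, 7 Wnt and 1 tuft cell genes were higher, and 0 oxidative phosphorylation and 0 interferon genes passed limma's test (3 higher and 4 lower at an unadjusted p under 0.05). Without glands a 5 interferon genes were lower, and 9 when adjusted over the list alone, 2 pit cell genes were lower and 1 parietal cell gene was higher. Without parietal a, without parietal b and without glands b the parietal cell count was 0, the enteroendocrine count 2, 2 and 3, and the count of higher Wnt targets 2, 4 and 2. Without glands a the enteroendocrine count was 2. The mast cell protease Cpa3 (-1.42, SE 0.27) was the single gene of the leukocyte list past the threshold. Further genes were the integrin Itga9, which rose by 3.10 (SE 0.53), Fam71a, which rose by 3.39 (SE 0.28), and Mogat1, Cyp2c65 and Aldh3a1, which fell by 5.68 (SE 0.72), 5.46 (SE 0.80) and 5.02 (SE 0.80) on the log2 scale.

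Apart from the leukocyte list, the lists described, 10 in number, passed camera with the preset correlation, and none with an estimated one, with adjusted p between 0.504 and 0.743. Lists for chief and mucous neck cells, stem cell candidates, BMP targets, FGF and MAPK feedback, Notch, endoplasmic reticulum folding, fatty acid oxidation, leukocytes, stroma, endothelium, pancreatic acinar cells, intestine and squamous forestomach did not pass. The counts were 0 higher and 2 lower genes without parietal replicate a, 0 and 2 without parietal b, 1 and 10 without glands b, and 47 and 362 without glands a. Of the named genes, 2 of the 28 that passed did so under every alternative. List calls ended without parietal a (parietal cell, adjusted p = 0.101; Wnt targets, 0.0691), without parietal b (metaplasia, 0.092), without glands a (metaplasia, 0.187), without glands b (parietal cell, 0.0729; interferon and MHC, 0.0801), without dim features (metaplasia, 0.165; interferon and MHC, 0.0921) and with all 13 arrays in 1 fit (parietal cell, 0.0695; Wnt targets, 0.0534). Calls were gained by the lists of intestine (without parietal b, 0.0274; without glands a, 0.00894), Notch (without glands a, 0.0279) and, without glands b, chief cells (0.00702), mucous neck cells (0.0189) and leukocytes (0.0388).

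The last comparison asked what changes in chief cell organoids when gastrin, FGF10, Noggin and Wnt3a are left out of the medium. In the list of pit cells, which line the mucous surface, 8 of 10 genes were higher in ER medium (list adjusted p = 0.483 with an estimated correlation). The mucin Muc5ac was 11.88 ± 0.95 (SD, n = 3) against 8.07 ± 1.60 (SD, n = 3), a log2 fold change of 3.82 (SE 0.79, limma adjusted p = 0.0156), and the gastrokines Gkn1 and Gkn2 rose by 3.69 (SE 0.63) and 3.15 (SE 0.80). Gastric intrinsic factor (Cblif) was lower, at 6.55 ± 2.82 against 11.09 ± 0.26 (-4.53, SE 1.20, adjusted p = 0.0373), as were Muc6 (-4.31, SE 1.01) and Pgc (-3.38, SE 0.64). Of the stem cell candidates 9 of 14 and of the Wnt targets 10 of 18 were lower (adjusted p = 0.397 for both lists with an estimated correlation), with Lgr5 at -4.21 (SE 0.84, adjusted p = 0.0135), Ascl2 at -3.07 (SE 0.42), Axin2 at -2.54 (SE 0.32) and Tnfrsf19 at -2.31 (SE 0.34, adjusted p = 0.00571). In the proliferation list 21 of 22 genes were lower, with Mki67 at -2.12 (SE 0.35), and the list's adjusted p was 0.397 with an estimated correlation. In all, 1721 genes were higher and 1899 lower in ER medium, which is 19.2% of 18820 genes, and 5993 had an unadjusted p under 0.05. These values come from the fit that left the pairing of the letters out. With the replicate letter as a block, 1944 genes were higher and 2500 lower.

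In the pit cell list Mucl3 (2.93, SE 0.72) was among the 8 higher genes, and that count was 1 without EGFNWR replicate a, 2 without EGFNWR b, 1 without ER a, 3 without ER c and 7 without EGFNWR c and without ER b alike. The lower proliferation genes included Ccna2 (-2.18, SE 0.34), Top2a (-2.06, SE 0.37) and Plk1 (-1.95, SE 0.33). The stem cell candidates, with Iqgap3 at -1.78 (SE 0.26), had 5 lower without EGFNWR a, and the Wnt targets also held Cd44 (-2.36, SE 0.50). Of the endoplasmic reticulum folding genes 16 of 19 were lower, including the chaperone components Sdf2l1 (-1.60, SE 0.22), Creld2 (-1.51, SE 0.18) and Hyou1 (-1.43, SE 0.21) and the stress-induced pseudokinase Trib3 (-1.44, SE 0.15). Among immediate early genes 7 of 16 were higher, with Ier3 at 1.03 (SE 0.12), Zfp36 at 0.93 (SE 0.11) and Fos at 0.86 (SE 0.15), while Jun was lower (-0.93, SE 0.14), and 2 were lower without ER b. Of the fatty acid oxidation genes 6 of 14 were higher, among them Slc25a20 (0.87, SE 0.13), Cpt2 (0.81, SE 0.17) and Acaa2 (0.81, SE 0.17), and the transcriptional coactivator Ppargc1a was lower (-1.73, SE 0.20); 3 were higher without EGFNWR b. Adjusted over the list alone, 9 pit cell, 9 immediate early and 7 fatty acid oxidation genes were higher, and 9 stem cell, 21 proliferation, 11 Wnt, 18 folding, 2 immediate early and 1 fatty acid oxidation genes lower. These 7 lists passed camera with the preset correlation, and none passed with an estimated correlation (adjusted p = 0.483 for pit cell and fatty acid oxidation genes and 0.397 for the others). With all 13 arrays in 1 fit the fatty acid oxidation list lost its call (adjusted p = 0.0729). The chief cell list, lower, gained one without EGFNWR a (0.0419), EGFNWR b (0.0394), ER b (0.00563) or ER c (0.0243), as did, higher, the interferon list without EGFNWR a (0.0419) or ER b (0.0081) and the tuft cell and squamous lists without EGFNWR c (0.00618 and 0.0439).

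Other lists did not pass as a whole but held single genes past the threshold. In the chief cell list 4 of 9 genes were lower, among them the secretory cell factor Bhlha15 (-2.63, SE 0.31), and the lipase Pnliprp2 was higher (2.64, SE 0.56). In the mucous neck cell list A4gnt (-3.78, SE 0.69) and Gkn3 (-1.99, SE 0.51) were lower and Tff2 was higher (1.99, SE 0.48). In the parietal cell list 4 of 16 were higher and 3 lower, including the water channel Aqp4 (2.15, SE 0.35), the exchanger Slc9a2 (1.10, SE 0.15), the muscarinic receptor Chrm3 (-2.13, SE 0.31) and the proton pump gene Atp4a (-0.83, SE 0.18). The metaplasia list had 2 of 10 higher and 4 lower, the latter Cftr (-3.35, SE 0.59), Cd44, Sox9 (-1.75, SE 0.24) and Gpx2 (-1.12, SE 0.24). Feedback genes of FGF and MAPK signalling split, with Dusp5 (1.52, SE 0.17), Phlda1 (0.82, SE 0.13) and Dusp4 (0.77, SE 0.14) higher and Etv5 (-1.69, SE 0.21) lower. Notch genes split as well, with Dll4 (1.24, SE 0.16) and Nrarp (1.20, SE 0.17) higher and Lfng (-1.52, SE 0.17) and Jag2 (-0.92, SE 0.21) lower. The BMP targets Smad7 (0.95, SE 0.11) and Id1 (0.49, SE 0.13) were higher. From the tuft cell, oxidative phosphorylation, interferon and MHC, leukocyte, intestine, squamous and endothelium lists came Avil (1.19, SE 0.17), Cox5a (0.54, SE 0.10), B2m (0.39, SE 0.09), Irf1 (0.44, SE 0.11), Cd68 (0.87, SE 0.16), Fabp2 (1.09, SE 0.20), Lgals4 (0.72, SE 0.14) and Krt4 (1.56, SE 0.43), which were higher. Esam (-1.09, SE 0.17) and Cd74 were lower. Cd74 lay between 3.51 and 4.02 in ER medium, below the array medians, and between 4.21 and 5.27 in EGFNWR medium, and Fabp2 lay between 3.54 and 3.98 in EGFNWR medium, so the size of both differences is open. Several of these counts moved with 1 array left out. Without EGFNWR a 2 chief cell genes were lower. Without each of EGFNWR a, EGFNWR b and ER a, 0 chief cell genes were higher, 1 mucous neck cell gene was lower in place of 3, 2 metaplasia genes were lower, and 2 Notch genes were higher in place of 4. Higher metaplasia genes numbered 0, 0 and 1 in those 3 fits. Lower Notch genes numbered 1 in place of 2 in those fits and without EGFNWR c, and lower FGF feedback genes 1 in place of 2 without ER a. Without any one array other than EGFNWR c, 0 mucous neck cell genes and 1 BMP target were higher, and 0 interferon and MHC genes were lower. Higher interferon and MHC genes numbered 2 with all arrays, 0 without EGFNWR a, EGFNWR b or ER a, 1 without EGFNWR c or ER c, and 8 without ER b. Krt4 was the 1 squamous gene, and that count was 0 without EGFNWR a, EGFNWR b, ER a or ER b and 3 without EGFNWR c, where 3 tuft cell genes were higher too. In the intestine list 1 gene was higher without EGFNWR a or EGFNWR b, and in the leukocyte list 2 were without ER c. No gene of the enteroendocrine, stroma or pancreatic acinar lists passed with all arrays and without a block. In lists with 0 lower genes otherwise, 1 acinar gene was lower without EGFNWR a and without ER b, 1 tuft cell gene without EGFNWR a and 1 oxidative phosphorylation gene without ER b. With the replicate letter as a block 18 further listed genes passed, all of them except Cela1 named here after their values were seen. Those higher were Gast of the enteroendocrine list (0.30, SE 0.08, adjusted p = 0.0496), Capn8, Dmbt1, Atf3, Sdhd, Irf7, Oasl2 and Krt13. Those lower were Cela1 of the acinar list (-0.80, SE 0.19, adjusted p = 0.0312), Clps, Ckb, Tert, Etv4, Il17rd, Notch1, Nr4a1, Dnajb9 and Canx. The folding gene Sec61b no longer passed (adjusted p = 0.0594). By the naming rule, the largest changes among the higher genes, beside Muc5ac, were Hsd17b6 (4.57, SE 0.81), Cyp2d34 (4.07, SE 0.56), the prostaglandin transporter Slco2a1 (3.82, SE 0.69), the water channel Aqp3 (3.75, SE 0.66) and Mettl7b (3.74, SE 0.62). Among the lower genes the potassium channel subunit Kcne3 (-4.17, SE 0.91) and Derl3, of protein degradation at the endoplasmic reticulum, (-3.94, SE 0.68) followed Cblif, Muc6 and Lgr5. The size of several of these changes is open, because Hsd17b6, Cyp2d34, Aqp3 and Mettl7b lay below the median on 2 of 3 EGFNWR arrays, and Lgr5, Ascl2, Axin2 and Tnfrsf19 on 2 of 3 ER arrays.

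ER replicate b lay between the media, with Cblif at 9.81 against 5.04 and 4.81 in the other ER arrays and Lgr5 at 7.80 against 4.33 and 4.50. EGFNWR replicate c was nearer to ER medium in genes higher there, with Hsd17b6 at 7.26 against 4.02 and 4.15 in the other EGFNWR arrays, Aqp3 at 6.82 against 4.19 and 4.22 and Mucl3 at 11.23 against 8.17 and 8.54. The counts fell to 874 higher and 1028 lower genes without EGFNWR replicate a, 1012 and 1044 without EGFNWR b, and 917 and 1029 without ER a. Of the named genes, 35 of the 68 that passed did so under every alternative.

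**Figure D3:**
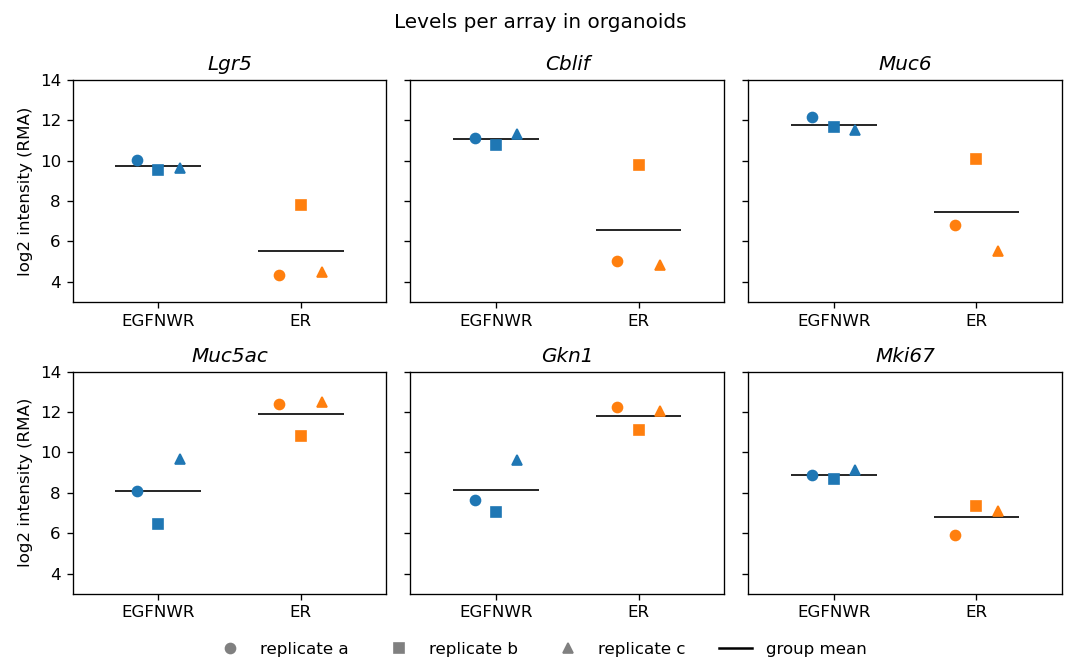
Log2 intensity (y axis) of 6 genes on each organoid array in EGFNWR and ER medium (x axis); symbols mark the replicate letter and horizontal lines the group mean. Lgr5 lies between 9.54 and 10.05 in EGFNWR medium and at 4.33, 7.80 and 4.50 in ER medium.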

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

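The tests of a chief array that is a mislabelled parietal library (both), of stromal cells in chief replicate b and of host genes as the whole cause, and the other choices of small RNAs, were chosen after the result was seen. So was the requirement, applied to every list median, that the members' interquartile range lie beyond a bound before an explanation is set aside; it left open the stromal cells and the mislabelled library, which the medians alone would have set aside.

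Probesets without a single gene name carry signal that the comparisons do not use: 236 of 14338 were higher and 342 lower in ER organoids. Of these, 181 higher and 213 lower had no name and 55 higher and 129 lower had several.

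Chief replicate c lay near the parietal arrays. If it were a parietal library, its chief cell genes should match theirs. Over 9 genes it stood 0.62 above the parietal mean (interquartile range 0.19 to 1.07). The parietal arrays differed by 0.19, and chief a and b stood 1.42 above. All 9 genes were higher in chief c than on either parietal array, from Pga5 at 8.90 against 7.22 and 7.25 to Clps at 13.41 against 13.40 and 13.26. That direction goes against a parietal library. The range begins at the difference between the parietal arrays, however, so this test leaves the label open. For a mixture of cells in the sort, the estimated parietal share was 0.863 (0.783 to 0.944) from 1025 genes higher in chief a and b. From 780 genes higher in parietal cells it was 0.64 (0.469 to 0.785), a gap of 0.223. Overlap of the ranges, set beforehand as the mark of a mixture, was met only barely. The genes were chosen by the difference between chief a and b and the parietal arrays, so chief c can lie between them without mixing. The estimate also takes chief a and b as free of parietal RNA, and their values go against that. Atp4b was 13.09 and 12.65 in chief a and b, and 13.22 and 13.29 in the parietal arrays. The estimated shares therefore place chief c between the 2 sets of arrays and do not measure its content of parietal RNA. The estimate does not decide for a mixture. Against a single parietal array the share of chief c was on average 0.327 below that of the other parietal array (a difference of -0.327), with ranges apart for parietal b (0.662, 0.502 to 0.815, against 1.06, 0.889 to 1.25) and overlapping for parietal a (0.583, 0.401 to 0.737, against 0.834, 0.655 to 0.986). A wrong label therefore stays open beside a mixed sort, and no biological explanation was tested.

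Chief replicate b held squamous keratins, with Krt5 at 11.85 and Krt14 at 10.04. Over 17 measured genes of a second squamous list of 18, none of them in the fixed lists, its median was 2.275 above the other chief arrays, higher than 100% of 10000 random lists matched on level, and 14 genes were over 1 higher; squamous cells in the sort, which was gated on the reporter, are a candidate source. Stromal cells stay open: the median of 11 stroma genes was 0.46 higher (0.31 to 0.57), above 99.8% of random lists. In chief b Lum, Pdgfra, Pdgfrb, Acta2, Myh11, Des and Postn lay between 3.51 and 4.80, below the array median. Signal is not shown to exceed background there, so this shift decides little. Col1a1 was 5.82 in chief b and 5.64 and 5.83 in the parietal arrays. Dcn stood out, at 8.47 in chief b against 6.22 and 4.58 in chief a and c. No biological explanation was tested.

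Of 59 small nucleolar and Cajal body RNAs, 16 were lower than in glands in chief cells and 27 in parietal cells. In 23 pairs of RNA and host, the host's log2 fold change against glands was subtracted from that of the RNA. The median of this difference was -1.33 (mean of the sorted groups). Interquartile ranges were -2.50 to -0.32 and -2.96 to -0.35. Over all 36 pairs the medians were -1.26 and -1.34, with ranges of -2.35 to -0.29 and -2.79 to -0.35. These values argue against a matching fall of host RNA as the whole cause. Over 14 pairs whose RNA was bright in sorted cells, however, the chief cell range reached 0.41. That choice leaves out the RNAs lowest there. Transcription of the host genes was not measured, and bright host genes have little room to differ, so lower transcription stays open. The host genes' own median was -0.10; this planned test left a part of the change open, because the RNAs' median of -1.42 in chief cells missed its bound. Lower recovery of small RNAs may contribute: 68.3% of 41 RNAs with a mean of at least 6 were at least 2-fold lower, and of all 59 RNAs 59.3% in chief and 61.0% in parietal cells, short of the share required. Low values were not limited to sorted cells. On the organoid arrays Snora33 lay between 4.38 and 5.68, Snord118 between 4.28 and 4.60 and Snora74a between 5.35 and 6.03. Snora69 lay between 6.23 and 7.63 there, above the sorted cells and below glands. The 2 experiments were not tested against each other, so the pattern may belong to the gland arrays as much as to sorting. Handling is confounded with sorting, and no biological explanation was tested.

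Of the 10 splits of the organoid arrays into 3 and 3, 1 gave as many genes as the real one, which is itself with 3620; the highest other gave 0, also among the 4 splits that part as many pairs. Splits are too few for a share under 0.05. Every other split also mixes the media, which adds their difference to the spread within a side, so its count of 0 decides nothing.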

How the results depend on the processing

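List tests under settings other than the estimated correlation, the block and the dim feature filter were chosen after the data were seen. Unless stated, the cause of a change was not tested. With an estimated correlation 0 lists passed in each comparison; the preset gave 12, 11, 10 and 7, of which 9, 6, 6 and 6 passed under every other alternative, and without chief replicate a 7 passed in chief cells against glands (range over arrays left out 7 to 15). Genes higher and lower in chief against parietal cells, 0 and 0, were 95 and 71 with all 13 arrays in 1 fit and ranged from 0 to 909 and 0 to 408 with an array left out. For chief cells against glands (24 and 66) array weights gave 42 and 105, all 13 arrays 400 and 815, and every probeset 6 higher. Only the 2 groups, which drops arrays and also changes the shared spread, gave 4 and 18. Leaving out a chief array gave 5 to 223 and 20 to 217. For parietal cells against glands (43 and 260) repeated quantile normalization gave 22 and 112, the dim feature filter 408 lower, array weights 1393 and 1808, all 13 arrays 1106 and 1601, only the 2 groups 1205 and 1508, every probeset 6 and 60, and leaving out arrays 0 to 47 and 2 to 362. Here too, fitting only the 2 groups drops the chief arrays and also changes the shared spread. A lone array of a group was assumed to vary like the other groups. For organoids (1721 and 1899) all 13 arrays gave 677 and 1028, a 2-fold threshold 418 and 523 by construction, and leaving out arrays 874 to 1628 and 1028 to 1889.

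With the replicate letter as a block, counts were 971 and 687 for chief against parietal cells, 130 and 94 for chief cells against glands and 564 and 1038 for parietal cells against glands. Whether equal letters mark paired arrays there was not settled. Chief c, alone in its block, drops out by construction. For the organoids, whose pairing by letter the labels do not state, the block gave 1944 and 2500 genes and changed no list call.

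Named genes that changed sign were not past the threshold under either setting. In chief against parietal cells Atp4a ranged from -0.28 to 0.02 with an array left out. In chief cells against glands, with arrays left out, Psca ranged from -0.01 to 0.145, Pcna from -0.06 to 0.115, Xbp1 from -0.23 to 0.335, Calr from -0.16 to 0.22 and H2-K1 from -0.68 to 0.07. With the block Psca was -0.01, Calr 0.22 and H2-K1 0.04, with centring Pcna was -0.0183 and Xbp1 -0.0133, and Calr was 0.0876 with repeated quantile normalization and 0.042 with array weights. No named gene past the threshold changed sign. Signal near the top of the scale limits differences of the brightest genes.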

Other observations

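The organoids differed from the tissue arrays in ways that belong to no comparison, because the 2 experiments were not tested against each other, and whether they were normalized together is not given in the sources used here. The chief cell chitinase Chia1 stood between 12.60 and 13.43 on the 7 tissue arrays and between 3.92 and 4.49 on the organoid arrays, and the proton pump gene Atp4b between 12.65 and 13.29 and between 4.27 and 4.72. Pga5 lay between 7.22 and 10.79 on tissue arrays and between 3.94 and 4.40 in organoids. The endocrine genes Chga and Sst stayed at or below 5.50 in organoids and at or above 9.00 in tissue. Other epithelial genes were brighter in culture, with Wfdc2 between 11.06 and 11.79 against at most 7.64 in tissue, Cldn7 between 8.95 and 9.93 against at most 5.19, and Vil1 between 9.82 and 10.06 against at most 8.18. The keratin Krt4 lay between 7.53 and 10.42 in organoids, and on tissue arrays it was 6.95 in chief replicate b and at most 4.12 elsewhere. These genes were chosen after their values were seen.

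The interferon genes Irf7 and Oasl2 were 8.69 and 9.91 in glands replicate b and 6.44 and 8.05 in glands replicate a, a difference within 1 group. Their levels in organoids were between 9.42 and 10.65 and between 9.80 and 10.97.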
